A study of Mus musculus with 2 samples.

How the data were processed

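The samples are 2 total RNA-seq libraries of mouse embryonic day 14.5 intestine, made from 10 ng of RNA longer than 200 nucleotides extracted with the Ambion mirVana kit, per the labels. A SmartSeq protocol is linked in the labels, without saying which of its steps applied. The replicate numbers are those of the labels. The labels give the same donor record for both and the same pup and dam numbers, with collection dates 2 days apart, so date and embryo cannot be separated.

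Per the file headers and the notes deposited with them, reads were aligned to mm10 with GENCODE M4 annotation and each library was quantified on its own. The quantification tool, its version and the use of strand are not given in the sources used here. Expected counts were deposited by the authors per gene and per transcript, and are not whole where reads were shared between features. TPM values were deposited by the authors over all features of a table, which include 96 spike-ins and 26248 features with numeric identifiers. FPKM values were deposited by the authors beside them and used only for an alternative correlation. The percent share of each isoform in its gene was deposited in the transcript tables. The deposited files also hold, taken here as scores, the bounds of an interval of each gene's TPM, which is centred on a posterior mean and need not contain the TPM itself. For all transcripts over 1000 bases, length minus effective length plus 1 was 100.

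Gene symbols, biotypes and coordinates came from GENCODE M21 on GRCm38, the same assembly as mm10 but a later annotation than the authors used. Of 43346 gene identifiers 42462 matched, and the other 884 held 0.202% of gene TPM. Spike-ins and numeric identifiers were left out of gene counts. Their shares matter for level, since TPM is a share of all features and spike-ins took 9.77% and 10.4% of it. Short genes gain TPM from few counts, as 121 genes with an effective length under 30 held 4576 TPM from 1205 counts in replicate 1.

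Replicates 1 and 2 had 32938592 and 32371363 estimated counts in genes. Intervals and floors cover counting error only, and amplified reads are not independent molecules. The floor was 3 counts per library, and folds against 0 counts are lower bounds at that floor. The common dispersion between libraries, from edgeR 4.0.16 on rounded expected counts of 19437 genes, was 0.0244, a coefficient of variation of 15.6%. Spread per library was the robust SD of log2 differences scaled to a library. For 53 spike-ins with mean TPM of at least 5 it was 0.0578 with a median difference of 0.10, against 0.106 and -0.05 for genes.

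The following choices were made before the data were examined. With 1 group there was no test between groups. Detection was TPM of at least 1 in both libraries. Correlation used log2(TPM + 1). A gene differed when its mean TPM was at least 5, its log2(TPM + 1) differed by at least 1 and its deposited 95% intervals did not overlap. A total of 38 gene lists with 627 entries, 613 different genes, were fixed for cell types, neighbouring organs and programmes, of which 606 genes were in the tables. A list stood above or below when its median passed percentile 97.5 or 2.5 of 10000 random lists of protein-coding genes of its size, and apart between embryos by the same limits among lists matched on mean expression (from the 100 nearest genes in level). About 5% of lists of unrelated genes pass such limits by chance. Members of a fixed list can vary together, so more of the fixed lists may pass. Percentiles describe these libraries and are no p-values. Hox detection was compared with a two-sided Fisher's exact test. The named genes were the 10 highest nuclear genes, the mitochondrial genes as a group, the 3 highest members of each list, members of cell identity lists under TPM 1 in either library where at most 4 exist, the highest Hox gene of each cluster with all of paralogs 12 and 13, the 10 largest differences per direction, all sex-linked members, and the highest multi-transcript member of each identity list. Some genes that this rule selects are not reported here. Other genes are named as chosen after their values were seen.

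Alternatives were other detection thresholds, an estimated count of 10, TPM rescaled over nuclear protein-coding genes, a pseudocount of 0.1, TMM factors from edgeR, size factors from DESeq2 1.42.0 and spike-in scaling, no filter on low values, posterior mean TPM, matching on length, and leaving out each library. Alternatives added after the values were seen left out the pancreas and sex-linked lists or members, and applied spike-in scaling to the lists. The rescaled log2 shifts of replicate 2 were 0.05 for TMM and for DESeq2 and -0.09 for spike-ins.

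The rules were tested on simulated libraries with the real means and library sizes and the common dispersion for all of 43346 genes. That spread is wider than the robust one measured for genes at mean TPM of at least 5. The rates below hold for the simulated setting only. Of 200 changed genes, the 2-fold rule called 99 of 100 changed 4-fold and 77 of 100 changed 2.5-fold, and 24 of 11295 unchanged ones, with exact Poisson intervals in place of the deposited ones. Of 200 unchanged lists of 15 genes drawn at random, 8 (4%) stood apart, and of 50 such lists shifted by 0.3 in log2, 43 (86%) did. A bar of 90% had been set for the shifted lists. It was missed, and was then dropped as a condition, so a list with a shift of that size can go unnoticed. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3.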

Results

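Total RNA from the intestine of B6NCrl mouse embryos at embryonic day 14.5 was sequenced as 2 libraries, which form the only group. The labels describe each as the intestine of a single pup, collected on day 17 (replicate 1) and day 15 (replicate 2) of the same month, and give the sex as pooled. The data therefore hold no contrast between conditions. The questions the design allows are which cell types and developmental programmes the tissue expressed, and how far the embryos agreed. The gene tables held 34504419 estimated counts in all features for replicate 1 and 34042802 for replicate 2. Synthetic ERCC spike-in RNA took 4.54% and 4.91% of these counts. A floor of 3 counts corresponded to a median of 0.0588 and 0.0584 TPM (transcript abundance as a share of all transcripts of a library, scaled to a fixed total) among genes at TPM 1 or more. Values below are the mean of both libraries ± SD (n = 2), and a gene is called detected at TPM 1 or more in both.

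At that threshold 14806 of 43346 genes were detected, among them 13173 of 21474 protein-coding genes and 205 lincRNA genes. A further 589 genes reached TPM 1 in replicate 1 only and 594 in replicate 2 only. Across the 15989 genes at TPM 1 or more in either library, log2(TPM + 1) correlated with Pearson's r of 0.979 and Spearman's rho of 0.981. This correlation is across genes, which are not independent replicates. The per-library spread of log2 values was 0.196 for 4087 genes with mean TPM from 1 to 5, 0.116 for 8166 genes from 5 to 50 and 0.0849 for 3158 genes at 50 or more. In these classes the ratio of TPM + 1 between libraries was within 1.95-fold, 1.33-fold and 1.197-fold for 95% of genes. The added 1 makes it smaller than the ratio of TPM itself, most of all at low levels. The count differences exceeded sampling noise, with a chi-square of 15.3 per degree of freedom over 17781 genes, so the libraries were not the same library deposited again.

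Protein-coding genes held 88.0% and 87.8% of gene TPM in replicates 1 and 2, and mitochondrially encoded genes 3.62% and 3.55%. The 10 nuclear genes with the highest levels included the cytoskeletal actin gene Actb at 6023 ± 470 TPM, the adult alpha globin gene Hba-a2 at 5041 ± 1257, the elongation factor gene Eef1a1 at 4790 ± 230, the cyclophilin gene Ppia at 4524 ± 47.4, the ribosomal protein gene Rpl41 at 3891 ± 275 and the histone gene Hist1h2ap at 3686 ± 299. The other 4 were Gm42418, the pseudogene Gm28437 and the near-identical signal recognition particle RNA genes Rn7s2 and Rn7s1. Gm42418 (chromosome 17, 39846958 to 39848788) is annotated as a lincRNA and was at 11451 ± 249 TPM. The origin of its reads was not tested, so its level need not be that of a lincRNA. Gm28437 was at 8377 ± 229 TPM, and Rn7s2 and Rn7s1 were at 7133 ± 311 and 7132 ± 310. The deposited 95% intervals in replicate 1 were wide for Gm28437, 2294 to 8914 TPM, Rn7s2, 1018 to 11489, and Rn7s1, 1980 to 12475, and narrow for Gm42418, 10966 to 11033. They were also narrow for Hba-a2, 4003 to 4096, and Hist1h2ap, 3757 to 3841, which belong to families of similar genes whose reads may be shared. All 15 mitochondrially encoded list members were detected, led by mt-Atp6 at 6674 ± 357, mt-Atp8 at 5033 ± 268 and mt-Rnr2 at 3761 ± 321 TPM. Their deposited 95% intervals in replicate 1 were narrow for mt-Atp8, 5008 to 5183 TPM, and mt-Rnr2, 3428 to 3468. They were wide for mt-Atp6, 4414 to 7300, mt-Co3, 1076 to 7684, and mt-Co2, 1271 to 3589. The levels of such genes are less certain than their ± values show, which leaves the mitochondrial share uncertain too. Whether their reads were shared with Gm28437 was not tested.

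All 30 genes of epithelial identity were detected, with a median of 32.3 ± 4.55 TPM, above 99.98% of random lists of protein-coding genes of equal size. The adhesion molecule gene Epcam (ENSMUSG00000045394.8, chromosome 17, 87635979 to 87651129) stood at 511 ± 8.15 TPM, the keratin gene Krt8 at 370 ± 62.0 and the tight-junction gene Cldn7 at 360 ± 18.9. Of 22 genes of absorptive enterocytes, 17 were detected. The lectin gene Lgals4 was at 529 ± 71.0 TPM, the apolipoprotein gene Apoa1 at 190 ± 41.6 and the fatty acid carrier gene Fabp1 at 98.6 ± 30.4.

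Genes of secretory lineages were detected in part. None of these lists stood above random lists, with percentiles of 77.9 for goblet, 17.3 for Paneth and 18.6 for enteroendocrine genes. Goblet cell genes were detected for 9 of 12 members, led by the trefoil factor gene Tff3 at 291 ± 60.2 TPM, Spink4 at 43.4 ± 23.5 and Agr2 at 38.6 ± 17.3. The main intestinal mucin gene Muc2 was at 1.05 ± 0.247 TPM, with 0.88 in replicate 1, where the deposited 95% interval is 0.876 to 2.52, and at 1.81 by posterior mean TPM, so its level depends on the estimate. Gfi1 and Zg16 were at 0.81 ± 0.382 and 0.12 ± 0.17. Paneth cell genes were detected for 5 of 10 members, with Habp2 at 21.6 ± 0.827, Defa24 at 14.3 ± 0.834 and Defa17 at 8.04 ± 3.63 TPM. The defensin genes form a family of similar sequences, so their levels are uncertain. Detection of these list members does not by itself show that Paneth cells were present. Enteroendocrine genes were detected for 10 of 22 members in both libraries, 10 in replicate 1 and 17 in replicate 2. Sct, which encodes the hormone secretin, led at 128 ± 35.5 TPM, ahead of the peptide YY gene Pyy at 16.3 ± 22.8 and the endocrine progenitor factor gene Neurog3 at 11.1 ± 6.41. Pancreatic transcripts were abundant in replicate 2 and near the floor in replicate 1, as described further on, and several of these hormones are also made in pancreatic islets.

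Of 15 genes of adult crypt stem cells and Wnt targets, 12 were detected, with Smoc2 at 156 ± 21.2 TPM, Sox9 at 32.9 ± 3.15 and Prom1 at 32.2 ± 1.07. The adult crypt marker gene Olfm4 was at 0.89 ± 0.269 TPM, Notum at 0.965 ± 0.106 and Sp5 at 0.59 ± 0.17. Of 10 measured genes of the fetal epithelial progenitor list 8 were detected. Clu was at 50.5 ± 12.7 TPM, Gja1 at 42.2 ± 0.948 and Spp1 at 36.7 ± 49.0, the last from 2.04 in replicate 1 and 71.3 in replicate 2. Il1rn and Sprr1a were at 0.125 ± 0.0778 and 0.97 ± 0.269.

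**Figure D1:**
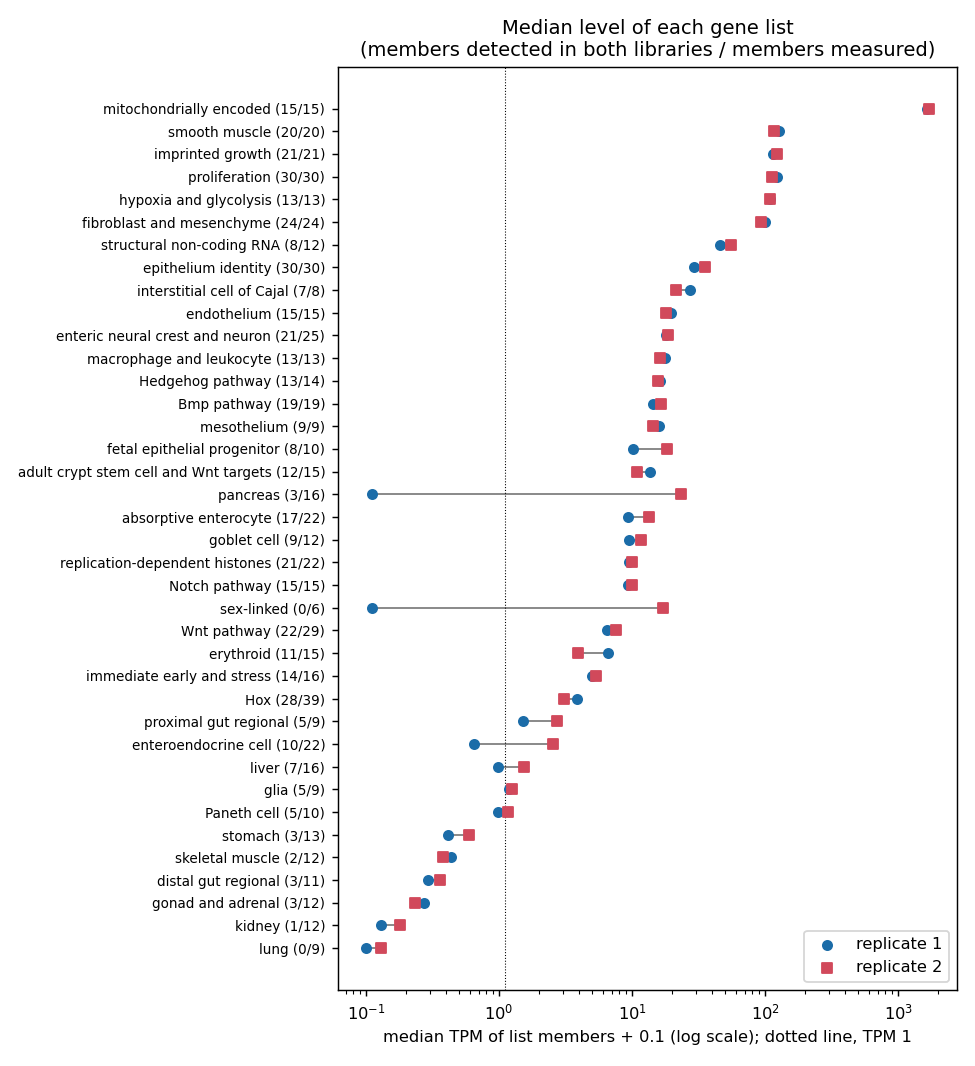
Median TPM of the members of each gene list, with 0.1 added, on a log axis; circles are replicate 1, squares replicate 2, and the dotted line marks TPM 1. The pancreas list runs from 0.01 in replicate 1 to 23.3 in replicate 2, and the smooth muscle list lies at 127 and 116.

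The mesenchyme and smooth muscle lists had the highest medians among the cell-type lists. All 24 fibroblast and mesenchyme genes were detected at a median of 96.4 ± 4.50 TPM, and all 20 smooth muscle genes at 121 ± 8.02, both at percentile 100 of the random lists. The collagen gene Col3a1 (ENSMUSG00000026043.14, chromosome 1, 45311538 to 45349706) was at 1584 ± 125 TPM, the matrix glycoprotein gene Sparc at 1111 ± 41.4 and Col1a1 at 685 ± 32.3. The contractile genes Acta2 (chromosome 19, 34241090 to 34255590), Myl9 and Actg2 were at 1556 ± 110, 1189 ± 77.5 and 1072 ± 11.02 TPM. Of 8 genes of interstitial cells of Cajal, the pacemaker cells of the gut, 7 were detected, with Etv1 at 37.2 ± 5.73, Ano1 at 31.7 ± 2.503 and Kit at 29.5 ± 1.01 TPM, and Hcn4 at 0.195 ± 0.0212. All 9 measured mesothelial genes were detected, with Krt7 at 80.2 ± 2.15, Upk3b at 62.4 ± 1.46 and Podxl at 31.4 ± 1.34 TPM.

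Enteric nervous system genes were detected for 21 of 25 members at a median of 18.1 ± 0.502 TPM. The endothelin receptor gene Ednrb was at 140 ± 14.8 TPM, and the neuronal genes Gap43 and Uchl1 were at 84.2 ± 4.09 and 81.0 ± 4.33. The 4 members under 1 TPM in at least one library were Chat at 0.735 ± 0.191 TPM, Nos1 at 0.75 ± 0.0849, Th at 0.955 ± 0.163 and Dbh at 1.24 ± 0.58. By posterior mean TPM, Nos1 was at 1.03 and Th at 1.42. The list stood at percentile 97.7 of random lists, just past the threshold, and no longer stood above it without replicate 2 or against expressed genes only. Glial genes were detected for 5 of 9 members, led by Fabp7 at 46.5 ± 1.05, Erbb3 at 24.9 ± 0.785 and Entpd2 at 5.25 ± 0.827 TPM. S100b was at 1.05 ± 0.127 TPM, Gfap at 0.34 ± 0.17 and Sox2 at 0.37 ± 0.0849.

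All 15 endothelial genes were detected, with Egfl7 at 104 ± 2.74, Cd34 at 43.9 ± 3.25 and Esam at 38.3 ± 1.98 TPM. All 13 measured macrophage and leukocyte genes were detected as well, with the lysozyme gene Lyz2 at 53.3 ± 4.94, the complement gene C1qb at 49.1 ± 0.00707 and Tyrobp at 42.4 ± 0.247 TPM. Erythroid genes were detected for 11 of 15 measured members. After Hba-a2 these were led by Hbb-bs at 2221 ± 665 and Hba-a1 at 1929 ± 486 TPM, while the erythroid regulator genes Klf1 and Gata1 were at 0.995 ± 0.559 and 0.475 ± 0.205, and Hemgn and Rhag at 0.27 ± 0.0849 and 0.265 ± 0.0495.

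Signalling pathways known to pattern the gut wall were broadly expressed. Hedgehog pathway genes were detected for 13 of 14 members, with Gas1 at 93.0 ± 1.73, the receptor gene Ptch1 at 40.1 ± 2.86 and Smo at 35.8 ± 0.962 TPM. Wnt pathway genes were detected for 22 of 29 members, with Ctnnb1 at 394 ± 22.1, Sfrp2 at 82.7 ± 3.63 and Sfrp1 at 81.7 ± 3.08. All 19 Bmp pathway genes were detected, led by the target genes Id2 at 400 ± 37.6, Id3 at 266 ± 15.7 and Id1 at 82.3 ± 3.75, and so were all 15 Notch pathway genes, with Hes1 at 50.3 ± 3.20, Rbpj at 32.98 ± 5.28 and Notch2 at 23.5 ± 0.226 TPM. None of these 4 lists stood above random lists at the median, with percentiles of 90.2, 66.4, 92.1 and 78.4.

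Proliferation, imprinted growth and hypoxia and glycolysis lists stood at percentile 100 of random lists. All 30 proliferation genes were detected at a median of 118 ± 7.33 TPM, with Cdk1 at 390 ± 14.9, Birc5 at 266 ± 0.368 and Pcna at 233 ± 0.297. All 21 imprinted growth genes were detected at a median of 119 ± 5.85 TPM, with H19 at 951 ± 12.6, Mest at 782 ± 3.35 and Igf2 at 771 ± 35.4. All 13 genes of hypoxia and glycolysis were detected at 109 ± 0.191 TPM, led by Ldha at 1922 ± 9.38, Eno1 at 1528 ± 1.62 and Aldoa at 909 ± 27.0. Replication-dependent histone genes were detected for 21 of 22 members, with Hist1h4d at 308 ± 7.17, Hist1h2ae at 185 ± 11.2 and Hist1h2bc at 76.2 ± 9.54 TPM, and the list stood at percentile 79.25. Immediate early and stress genes were detected for 14 of 16 members, with Ier2 at 58.4 ± 0.962, Jun at 46.2 ± 3.37 and Btg2 at 26.4 ± 0.969, and stood at percentile 52.55. Structural non-coding RNAs were detected for 8 of 12 measured members, with Malat1 at 3356 ± 469 TPM after both Rn7s genes. In all, 9 of the 38 lists stood above random lists (epithelial identity, enteric nervous system, mesenchyme, smooth muscle, proliferation, imprinted growth, hypoxia and glycolysis, mitochondrially encoded and structural non-coding RNA) and 2 stood below, kidney and lung.

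Hox genes, which mark position along the body axis, were detected for 28 of 39 members. By paralog number, 9 of 12 genes of paralogs 1 to 4 were detected, 11 of 11 of paralogs 5 to 8, 8 of 10 of paralogs 9 to 11 and 0 of 6 of paralogs 12 and 13. In the comparison fixed beforehand, 23 of 27 genes of paralogs 1 to 9 and 5 of 12 of paralogs 10 to 13 were detected (two-sided Fisher's exact test across genes, p = 0.0170), a contrast that lies in paralogs 12 and 13. This test no longer passed at a detection threshold of TPM 5, with 13 of 27 against 2 of 12 genes and exact p = 0.0832. The highest gene of each cluster was Hoxb5 at 39.8 ± 1.29 TPM (chromosome 11, 96303336 to 96306121), Hoxa5 at 25.2 ± 2.11, Hoxd3 at 21.7 ± 0.339 and Hoxc4 at 11.9 ± 0.594. Among paralogs 12 and 13, Hoxa13 was at 0.295 ± 0.0212 TPM, Hoxd12 at 0.225 ± 0.0495, Hoxd13 at 0.02 ± 0.0283 and Hoxb13 at 0.01 ± 0.0141, and Hoxc12 and Hoxc13 had 0 counts in both libraries. Neighbouring Hox genes share regulation, so they are not independent observations. Genes typical of proximal gut were detected for 5 of 9 members, with Fabp1, Gata4 at 25.02 ± 5.40 and Adh1 at 14.9 ± 4.41 TPM. Genes typical of distal gut were detected for 3 of 11, among them Hoxd10 at 8.45 ± 3.37 and Hoxd11 at 3.04 ± 0.354.

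**Figure D2:**
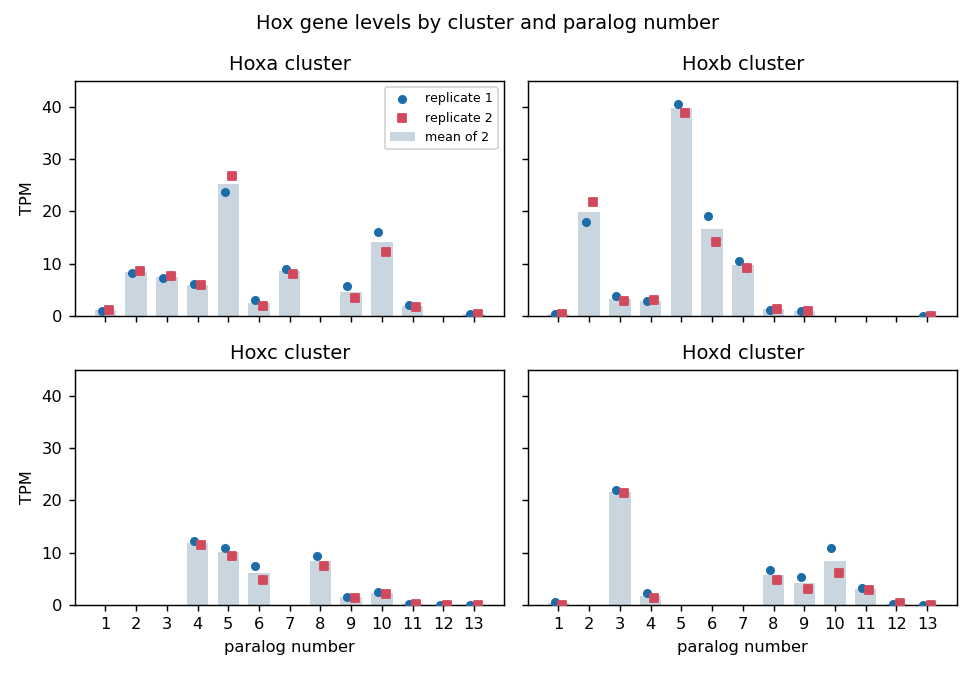
TPM of each Hox gene by cluster and paralog number; bars are the mean of both libraries, circles replicate 1 and squares replicate 2. Hoxb5 is the highest at 39.8 TPM, and no gene of paralogs 12 and 13 reaches TPM 1.

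Markers of neighbouring organs were mostly low, with pancreas in replicate 2 as the exception. Of 90 such genes 19 were detected in both libraries, 22 reached TPM 1 in replicate 1 and 34 in replicate 2. Pancreas genes were detected for 3 of 16 members in replicate 1 and 14 in replicate 2. Liver genes were detected for 7 of 16 members, with Trf at 67.2 ± 7.65, Serpina1b at 46.0 ± 0.403 and Ttr at 37.1 ± 10.1 TPM. Stomach genes were detected for 3 of 13, with Tff1 at 17.9 ± 2.93, Pgc at 1.84 ± 0.29 and Tff2 at 1.59 ± 0.0141. Gonad and adrenal genes were detected for 3 of 12, with Fgf9 at 16.8 ± 0.714, Cyp11a1 at 2.88 ± 0.742 and Star at 1.30 ± 0.156. Skeletal muscle genes were detected for 2 of 12, with Mylpf at 7.96 ± 0.962, Tnnt3 at 1.11 and 1.85 and Acta1 at 1.09 ± 0.141, the last below 1 in replicate 2. Kidney genes were detected for 1 of 12 (Cited1 at 4.05 ± 0.332 TPM, with Nphs1 at 0.535 ± 0.757 and Pax8 at 0.265 ± 0.134), and lung genes for 0 of 9, with Foxj1 at 0.755 ± 0.00707, Sftpc at 0.06 in both libraries and Sftpb at 0.045 ± 0.0636.

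The embryos differed in sex-chromosome transcripts. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254), had 77.2 TPM in replicate 1 and 0.06 in replicate 2, from 31487 and 24.8 estimated counts. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d had 0 counts in replicate 1 and 46.5, 28.2 and 18.0 TPM in replicate 2, at least 514-fold, 879-fold and 508-fold higher against a floor of 3 counts per library. Uty had 1 count in replicate 1 and 1245 in replicate 2. Tsix, antisense to Xist, had 5.09 and 0.02 TPM, and its reads cannot be separated from those of Xist unless strand was used in counting. Replicate 1 thus had Xist with almost no Y-linked counts and replicate 2 the reverse, while the labels give both sexes for each.

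Genes of the exocrine and endocrine pancreas formed the other large difference. Ctrb1, which encodes the digestive enzyme chymotrypsinogen B (ENSMUSG00000031957.5, chromosome 8, 111686519 to 111691010), had 0 counts in replicate 1 and 5554 in replicate 2 (300.1 TPM), at least 1831-fold higher. The pancreatic lipase-related gene Pnliprp1 was 213-fold higher (1.67 and 355 TPM). The insulin gene Ins2 had 0 and 1323 counts, with deposited interval bounds of 0.382 to 1.959 TPM in replicate 1 and 145 to 162 in replicate 2. The lipase gene Cel had 1 and 1978 counts, a ratio of 1956 with a counting interval of 351 to 77293. The amylase genes Amy2a5, Amy2a2, Amy2a4 and Amy2a3 had 0 counts in replicate 1 and 79.7, 77.7, 77.7 and 77.7 TPM in replicate 2. They are near-identical, so the split between them is uncertain. Pancreas list genes held 0.000994% of gene TPM in replicate 1 and 0.113% in replicate 2.

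In all, 56 of 11324 genes with a mean TPM of at least 5 differed by 1 or more in log2(TPM + 1) with deposited intervals that did not overlap. Of these 51 were higher in replicate 2 and 5 lower. Among them 11 were in the pancreas list, 5 in the sex-linked list, 5 in the enteroendocrine list and 2 in the goblet list. Besides Xist, those lower in replicate 2 were the pseudogene Ywhaq-ps3 (10.3 and 0 TPM), the X-linked gene Xlr3b (9.77 and 3.65), Gm10134 (12.2 and 4.98) and the small RNA gene Gm27845 (55.7 and 9.77 TPM, from 19.4 and 3.44 counts). A simulation with the same depth called 24 of 11295 unchanged genes. It gave every gene the common dispersion, a coefficient of variation of 15.6%, and used Poisson intervals in place of the deposited ones. Genes at mean TPM 5 or more had a robust SD of log2 of 0.106 per library, a narrower spread. The 24 calls therefore do not estimate false ones among the 56. Each embryo has 1 library, so none of these differences has a replicate check and no p-value is given.

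**Figure D3:**
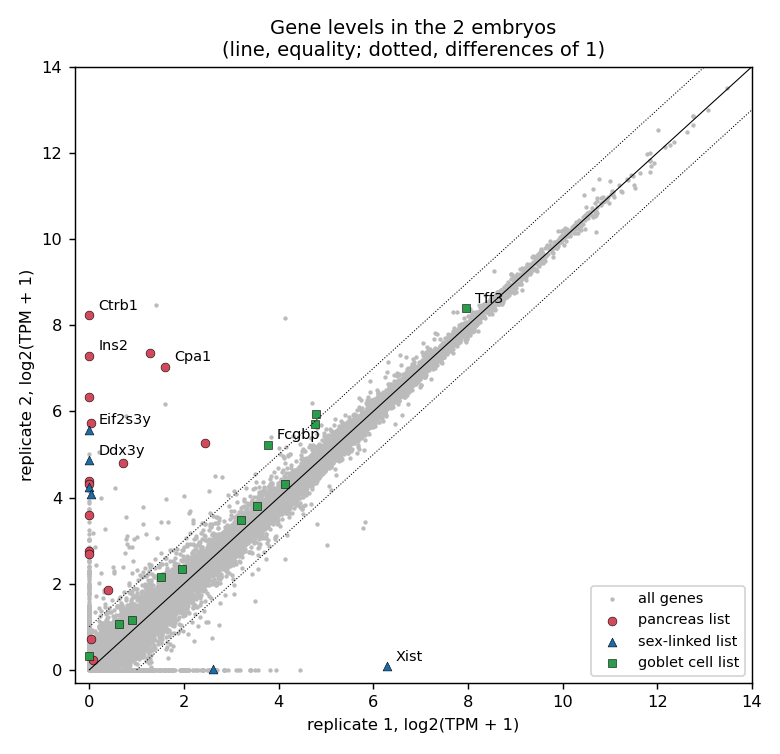
log2(TPM + 1) of each gene in replicate 1 (x axis) and replicate 2 (y axis), with the solid line at equality and dotted lines at differences of 1. Pancreas list genes lie along the left edge above the line, Y-linked genes likewise, and Xist lies at the lower right with 77.2 and 0.06 TPM.

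Among 32 lists with at least 5 expressed members, 13 differed between the embryos beyond the central 95% of 10000 random lists matched on expression. Of these 9 were higher in replicate 2 and 4 lower, relative to a median difference over genes at mean TPM 5 or more of -0.05 in log2. Pancreas genes led with a median difference of 4.34, with 14 of 14 expressed members higher. The sex-linked median of 4.15 reflects 4 members higher and 2 lower. Enteroendocrine genes had a median difference of 0.96 with 15 of 15 higher, for example Pyy with 1 and 347 counts and Neurog3 with 6.57 and 15.6 TPM. Members count as expressed at mean TPM 1 or more. Some members of both lists entered only through replicate 2, which fixes their direction. Without that filter the enteroendocrine median was 0.79 over 22 members and the pancreas median 4.19 over 16, both at percentile 100. With pancreas list members and the 2-fold different genes left out, a check chosen after the values were seen, the enteroendocrine median was 0.62 over 10 genes, still at percentile 100.

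Among epithelial lists, goblet genes had a median difference of 0.41 with 10 of 10 members higher, for example Tff3 with 249 and 334 TPM and Spink4 with 26.7 and 60.0. Enterocyte genes had 0.29 with 13 of 17 higher, epithelial identity genes 0.12 with 24 of 30 higher, and proximal gut genes 0.60 with 6 of 6 higher, for example Fabp1 with 77.1 and 120 TPM. Erythroid genes had 0.40 with 9 of 11 higher and Notch pathway genes 0.09 with 9 of 15 higher. These values use TPM as deposited, and small ones depend on the scaling, with a Notch median of 0.00992 and an epithelial identity median of 0.0357 under spike-in scaling and of 0.128 and 0.173 under TMM. The Hox list was lower in replicate 2, with a median of -0.18 and 22 of 29 members lower, for example Hoxd10 with 10.8 and 6.07 TPM. The shift was not shared by all paralogs. For paralogs 1 to 4 the median was 0.02 with 5 of 10 lower. It was -0.20 with 9 of 11 lower for paralogs 5 to 8, and -0.30 with 8 of 8 lower for paralogs 9 to 11. Proliferation genes had -0.12 with 28 of 30 lower, smooth muscle genes -0.13 with 17 of 20 lower, and adult crypt and Wnt target genes -0.16 with 8 of 12 lower. The last of these was at percentile 2.36, close to the limit of 2.5, and at 6.35 by the mean, 23.2 without the filter on low values, 3.93 with random lists matched on length, and 2.55 and 2.67 under TMM and spike-in scaling. The Hox list no longer stood apart with members at mean TPM 5 or more, at percentile 4.45, or without the filter on low values, at 8.61, nor did the Notch list by the mean. Too few proximal gut genes reached mean TPM 5 for that list to be tested at that level.

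**Figure D4:**
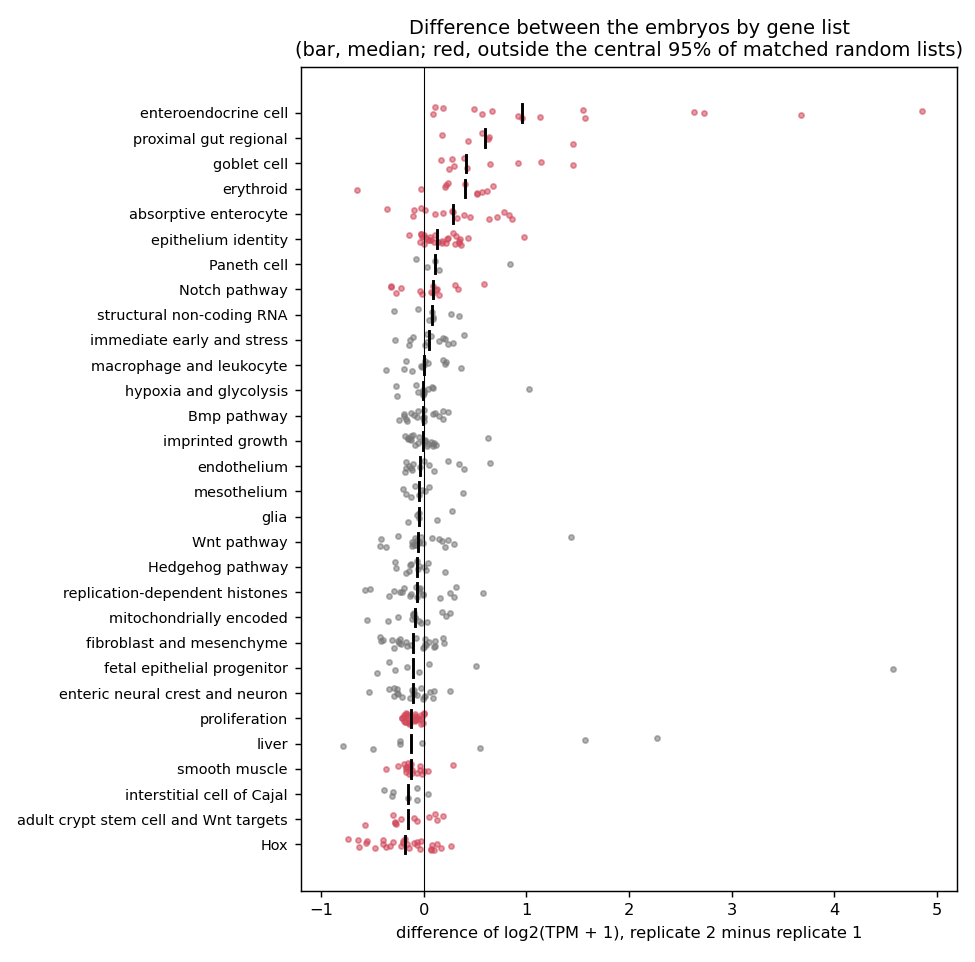
Difference of log2(TPM + 1), replicate 2 minus replicate 1, for each expressed member (points) of the lists, with bars at the median; red lists lie outside the central 95% of matched random lists. The pancreas and sex-linked lists, at 4.34 and 4.15, are left out, and the medians run from -0.18 for Hox to 0.96 for enteroendocrine genes.

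Transcript usage was largely shared. Of 7999 genes with at least 2 annotated transcripts and TPM 5 or more in both libraries, 7450 (93.1%, Wilson 95% interval 92.6% to 93.7%) had the same leading isoform in both. The interval treats genes as independent and does not measure how agreement varies between embryos. The leading isoform held a median share of 70.3% in replicate 1, against 39.5% for genes whose leading isoform differed. Among the highest multi-transcript genes of the cell identity lists, the leading isoform held 74.8% ± 1.02 (SD, n = 2) for Cldn7, 82.0% ± 1.47 for Lgals4, 98.2% ± 0.177 for Spink4, 65.6% ± 2.05 for Col3a1, 98.5% ± 0.247 for Myl9 and 94.1% ± 0.891 for Prom1. It held 55.6% ± 3.54 for Ednrb, 43.3% ± 0.0283 for Krt7, 24.2% ± 3.69 for Egfl7 and 80.4% ± 9.93 for Habp2, and over 90% for Sct, Clu, Fabp7, Hba-a2 and Fcer1g. For Etv1, with 13 annotated transcripts, the isoform leading in replicate 1 held 33.4% there and 24.1% in replicate 2, where another led.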

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

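The tables list 26248 features with numeric identifiers and a median length of 73 bases, which the comparisons leave out and whose identity is not stated in the sources used here. They held 31 estimated counts in replicate 1 and 30 in replicate 2, above the limit of 3 that a count of 0 allows. The counts lay in 5 features in replicate 1 and 6 in replicate 2, with 4 in both. The only group has 2 samples, too few for a search for outlying ones, and there was no contrast to compare between groups.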

How the results depend on the processing

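No paired analysis was possible because there is 1 group. The number of detected genes, the 2-fold set under 6 of 7 alternatives, and both list counts stayed within 1.5 times of the values reported, with 8 to 13 lists above other genes and 12 to 15 apart between embryos. Organ markers detected in both libraries numbered 46 at TPM 0.1, 9 at TPM 5 and 36 at an estimated count of 10, and from 22 to 34 when a library was left out, with the threshold or the missing library as the cause by construction. The Hox comparison kept its direction and had exact p = 0.0832 at TPM 5, where fewer genes count as detected. Correlation was 0.944 with a pseudocount of 0.1 and 0.992 with no filter on low values. Without that filter 116 genes differed 2-fold (105 higher in replicate 2 and 11 lower), all 56 among them. Isoform agreement was 90.8% at gene TPM 1 and 95.3% at TPM 20. For these the cause was not tested. Without the pancreas and sex-linked lists 40 genes remained, 36 higher and 4 lower. Pnliprp1 and the amylase genes Amy2a2, Amy2a3 and Amy2a4 are not in the pancreas list and stayed among the 36. The 40 are therefore not free of pancreas genes.

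Lists above other genes numbered 8 without replicate 2, which lost the enteric nervous system, and 10 without replicate 1, which added pancreas. Levels of single genes and lists moved by less than their SD in 211 of 211 cases when a library was left out, which follows from a mean of 2. Rescaling over nuclear protein-coding genes multiplies all levels by 1.31, and moved 159 of 211 by over 1 SD, and posterior mean TPM moved 49, with 124 the same. Genes with mean TPM from 1 to 5 were the least precise, with 95% within 1.95-fold in TPM + 1, and the cause was not tested. Depth sets the floor of 3 counts, a median of 0.0588 TPM in replicate 1.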

Other observations

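The genes in this paragraph fall outside the rule for naming and were chosen after their values were seen. The sucrase gene Sis and the trehalase gene Treh had 0 counts in both libraries, with floors of 0.0387 and 0.0824 TPM in replicate 1, and the lactase gene Lct was at 0.245 ± 0.00707 TPM. The apolipoprotein gene Apob was at 31.4 ± 1.67 and the alkaline phosphatase gene Alpi at 9.80 ± 4.41. Outside the lists, genes higher in replicate 2 included Serpina6 (0.71 and 58.8 TPM), Clps (16.6 and 287), Gc (0.18 and 15.0), S100a8 (2.06 and 14.5) and Cebpb (2.18 and 9.73).

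The tests in this and the next paragraphs were all chosen after the results were seen. Each library showed the transcripts of a single sex. Tissue of both sexes in each library was argued against by the 95% upper bounds of the minor pattern, 0.0784% for Y-linked genes in replicate 1 and 0.119% for Xist in replicate 2, relative to the other library. The pooled-sex label may therefore describe the collection and not each library, and no biological explanation was tested.

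Pancreas genes were higher in replicate 2. A difference in sequencing depth was argued against by a ratio of total counts of 0.987, and reads shared between near-identical copies by a median difference of 4.08 over 9 members without such copies, the lowest 1.45. Pancreatic tissue in the replicate 2 sample is a candidate explanation. A further list of pancreas genes lay at percentile 100, with 16 of 19 higher and a median of 0.74. It would rise with any source of pancreatic RNA in replicate 2, so it cannot tell tissue in the sample from another source. That list was weaker than the other and mixed. Rbpjl (0.05 and 8.05 TPM) and Reg1 (0 and 5.15) rose, Spink1 (95.04 and 134.7) and Sycn (12.3 and 13.9) were expressed in both, Pla2g1b (4.61 and 3.40), Ctrl (0.93 and 0.65) and Dnase1 (5.85 and 3.46) were lower in replicate 2, and Ctrc and Cuzd1 had 0 counts in both. The sex of the embryo cannot be told apart from it, with 1 library of each sex.

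Goblet, enterocyte and adult globin genes were also higher in replicate 2. More epithelium in replicate 2 stayed open for both epithelial lists. The median differences of goblet and enterocyte genes exceeded that of epithelial identity genes by 0.28 and 0.16 log2 units, within the larger robust SD across list members, 0.295 and 0.466. That SD describes single members and is not the error of a median, so this comparison cannot decide. More proximal intestine in replicate 2 stayed open as well. With the split of the design, the median of expressed Hox genes of paralogs 10 and 11 differed by -0.10 from that of paralogs 1 to 9 (robust SD 0.304). A split after paralog 8, chosen after the values were seen, gave -0.20 (robust SD 0.288). Here too the SD is that of single members and cannot decide. All 5 expressed genes of paralogs 10 and 11 were lower in replicate 2. So were all 8 of paralogs 9 to 11, at percentile 0.34 of matched random lists. Of paralogs 1 to 4, 5 of 10 expressed genes were lower. For adult globins, an equal rise of all blood cells was argued against. Adult globins were 1.46 times as high in replicate 2 relative to embryonic globins, with 8896 and 12986 TPM against 640.7 and 640.6. The ratio cannot exclude more of only those blood cells that make adult globins, and 9 of 11 expressed erythroid genes were higher. A later developmental stage of the replicate 2 embryo may contribute but cannot be told apart, with 1 embryo per library.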
